A study of Drosophila melanogaster with 4 samples.

How the data were processed

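ChIP-seq was carried out on CME-W1-Cl.8+ cells with an antibody to RNA polymerase II phosphorylated at serine 5 of its C-terminal repeat. Per the labels' protocols, cells were fixed with 1.8% formaldehyde for 10 min, and sonicated chromatin was incubated with the antibody for 15 h. The series holds 4 samples, 2 of ChIP DNA and 2 of input DNA, and groups and replicate numbers were taken from the sample titles. Cluster lists were analysed for ChIP replicate 1, ChIP replicate 2 and the combined list of the series. No list of the input libraries was analysed here, so input enters only as far as the authors used it in calling. Nothing says whether the replicates were separate cultures.

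Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes, which name the tool without its settings. Coordinates are on FlyBase release 5, per the file headers, and regions are described there as significantly enriched or, for a few, depleted. The region caller, its threshold, the filters on reads, the input library used for each list and the way the combined list was made are not given in the sources used here. Each replicate list belongs to a single library, whereas the combined list belongs to the series. The deposited score of each region is the authors' value, and its scale is not given in the sources used here. In all 3 lists, pairs of scores lay exactly 1, log2(3/2) or log2(4/3) apart (tolerance 1e-08) far more often than at steps of natural or decimal logarithms: scores that differed by log2 of 2 numbered 116 pairs in replicate 1, 82 in replicate 2 and 39 in the combined list, against 0 pairs at the natural logarithm of 2 in each. The scores thus have the steps of log2 values of ratios of whole numbers, but the quantities in the ratio are unknown, and scores were compared only within a list, to describe and rank regions and, in the closing observations, to set X clusters against autosome clusters by score level and by tied scores. No read counts were given, so the depth of each library is unknown, and intervals and p-values carry no information on it. A caller's threshold acts on depth, so a deeper or cleaner library can list more and wider clusters at the same occupancy.

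Regions with a positive score were analysed as clusters. The 1 depleted region of replicate 2 and the 18 of the combined list were kept apart. In replicate 2 and in the combined list 1 region each ran past the end of chromosome 4 and was counted as deposited. Clusters were counted as shared at an overlap of at least 1 bp. By chromosome and window, clusters found in both replicates were those of replicate 1 that overlapped one of replicate 2. Overlap of the replicates and the Jaccard index of covered bases were set against 1000 circular shifts of one list within each chromosome sequence (one-sided). Shares have Wilson 95% intervals, which treat clusters as independent. Clusters were ranked by score within each list, and the highest and lowest of 4 equal groups were compared with Fisher's exact test (two-sided). Windows of 1 Mb on X and on the 4 large autosome arms were compared with 100000 permutations of the windows (two-sided), with Benjamini-Hochberg adjustment over 8 tests. That test took the place of a planned comparison of transcription start sites and was chosen after the densities had been seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The overlap and window tests were tried on simulated lists, with 4482 clusters where overlap was simulated. A simulated overlap of 80.5% was recovered as 80.5%. The simulation nearly fixed this, as shared clusters were copies moved by far less than their width. Of 50 pairs of unrelated lists, 3 gave p under 0.05, and the window test called 2 of 50 simulations without a difference between X and autosomes. The simulated clusters were narrow and placed at random, without the uneven density of the real lists along the arms. These rates thus need not hold for the real lists.

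The rule for named regions was fixed before the data were examined. It asked for genes where an annotation of the same release was at hand and otherwise for the 20 highest scoring combined-list clusters found in both replicates and the 5 widest, by position. The reference table used here is on release 6, and positions were not converted between releases, so the position rule was followed. For the same reason the planned results on transcription start sites, the extent of clusters around them, gene bodies, the 27 gene lists and core promoter motifs were not computed. Alternatives covered a stricter score threshold, other overlap rules, merging of clusters within 1 kb, a width minimum of 500 bp, the large arms alone, ranking by width, the combined list in place of clusters found in both, and each replicate alone. 2 further alternatives, windows of 2 Mb and the window comparison without its 2 poorest windows, were chosen after seeing the data.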

Results

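RNA polymerase II carrying phosphoserine 5 in the heptad repeats of its C-terminal domain was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in CME-W1-Cl.8+ cells, a Drosophila melanogaster line also called Clone 8. The labels trace the line to the dorsal mesothoracic (wing) disc of male larvae in the third instar. This phosphorylation is placed on the polymerase around the start of transcription, so the question the design addresses is where in the genome of these cells the polymerase carried it. The series held 2 ChIP libraries made with the rabbit polyclonal antibody ab5131 and 2 libraries of input DNA. Each ChIP library had a list of enriched clusters, and a combined list was given for the series. The input libraries had no list of their own here. No read counts were given, so the depth of each library is unknown. All cells were of 1 kind, and the comparisons were those between the replicates, between the lists, between regions and between chromosomes. Positions are on FlyBase release 5, and regions are named by position because the gene table used here follows another release.

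The modified polymerase occupied many separate sites, most of them a few kilobases wide. Replicate 1 listed 5091 enriched clusters and replicate 2 listed 4876, a mean of 4984 ± 152 (SD, n = 2). The median cluster was 2.57 ± 0.053 kb wide (SD, n = 2), with quartiles of 2.09 and 4.00 kb in replicate 1 and of 2.13 and 4.21 kb in replicate 2. Together the clusters covered 19.1 ± 0.333 Mb over all sequences (SD, n = 2). Those on the 5 large chromosome arms covered 15.6% of these arms in replicate 1 and 15.3% in replicate 2. The combined list held 5309 clusters over 21.9 Mb of all sequences, and those on the large arms covered 17.7% of these arms. A small number of broad domains stood beside the narrow sites. In replicate 1, 45 clusters were wider than 20 kb, and in replicate 2, 46 were. The widest 10% of the clusters held 32.4% of the covered bases in replicate 1 and 31.4% in replicate 2. Across the clusters of a list, which are not independent replicates, wider clusters had higher scores (Spearman's rho 0.64 in replicate 1 and 0.61 in replicate 2). The score is the authors' own value for each cluster and scores were compared only within a list.

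The highest scoring sites were a few kilobases wide, somewhat wider than the typical cluster. The 20 clusters with the highest combined-list scores among those found in both replicates were between 2.24 and 12.3 kb wide, and their scores ran from 3.39 to 4.48. Their median width was 3.55 kb, against 3.11 kb for all combined-list clusters found in both replicates and 2.63 kb for the whole combined list. Of these, 7 lay on 2L, 4 on 3L, 3 on 2R, 3 on 3R, 1 on X and 2 on the unplaced sequence U. The highest score, 4.48, belonged to a 4.92 kb cluster on 2R from 13029712 to 13034632. It ranked second by score in replicate 1 and first in replicate 2, and its deposited start differed between the replicates by a single base. On 2L, a 2.77 kb cluster from 13214654 to 13217422 scored 4.37, and a 2.84 kb cluster from 13243268 to 13246110 scored 4.14. The same arm carried a cluster from 21213722 to 21216374, with a score of 4.23, and one from 21538352 to 21542656, with a score of 4.13. On 3R, the cluster from 19683870 to 19686606 scored 4.18, and on 3L the clusters from 3089642 to 3092284 and from 11242576 to 11251134 scored 4.08 and 4.00. The highest cluster outside the large arms lay on U from 9709786 to 9712860 and scored 3.87. The next cluster in score, on 3R from 17120854 to 17133202, was the widest of the 20 and the exception in shape, being 3 clusters in replicate 1 and 1 in replicate 2. The other 19 were each a single cluster in both replicates.

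The remaining 10 of these sites scored between 3.39 and 3.64. They lay on 3L from 8667790 to 8674402 and from 3069164 to 3072372, on 2R from 15612978 to 15617208 and from 5439056 to 5443794, and on 3R from 11066770 to 11073866. On 2L they ran from 900274 to 902770, from 20158266 to 20160506 and from 3477250 to 3481148. The X site ran from 5320198 to 5328096 and the second U site from 9177520 to 9179922. Each of the 20 sites stood near the top of each replicate list, with score ranks no lower than 35 in replicate 1 and 42 in replicate 2. The combined list shares most of its clusters with the replicate lists, so these ranks are not independent support.

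The 5 widest clusters were broad domains on 3L and 3R, with scores from 1.03 to 1.68 against a median of 1.03 for the combined list. The widest cluster of each list lay on 3L and was 122 kb wide, from 22279764 to 22402154 in the combined list. It was unbroken in both replicates, at 122.026 kb in replicate 1 and 122.283 kb in replicate 2, and its combined-list score was 1.54. A 58.7 kb cluster on 3R from 19114128 to 19172826, with a score of 1.68, was likewise a single cluster in both replicates. The other 3 of the 5 widest were broken up in at least 1 replicate. The 98.3 kb cluster on 3R from 21340610 to 21438924 was 2 clusters in replicate 1 and 3 in replicate 2. The 95.1 kb cluster on 3L from 5147606 to 5242676 was 2 and 8 clusters, and the 92.1 kb cluster on 3R from 4892760 to 4984832 was 1 and 4 clusters.

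**Figure D1:**
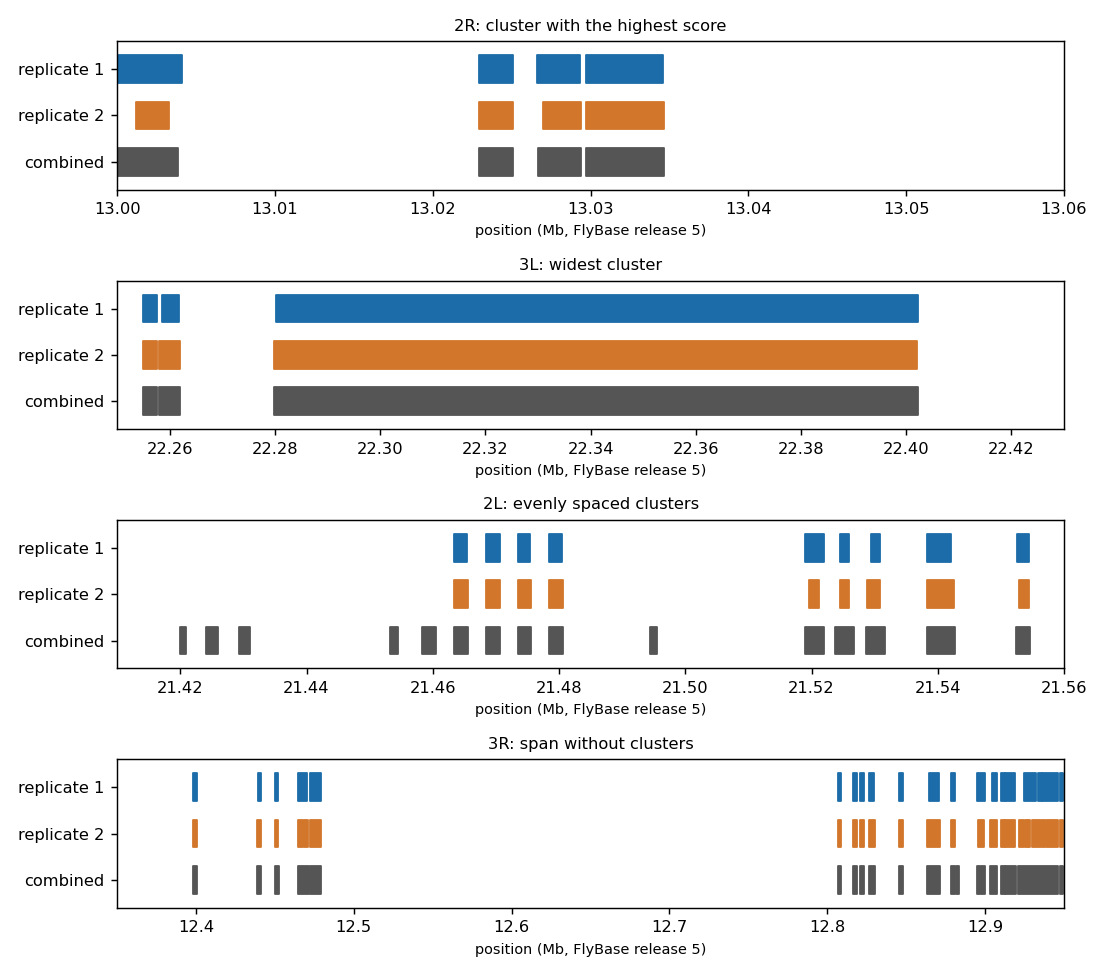
Clusters of replicate 1 (blue), replicate 2 (orange) and the combined list (grey) as bars against position in Mb on FlyBase release 5, in 4 stretches of 2R, 3L, 2L and 3R. The widest cluster, on 3L, is unbroken in all 3 lists, the 2L stretch holds 4 evenly spaced clusters in each replicate, and the 3R stretch holds a span with no cluster in any list.

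The replicates marked largely the same places. Of the 5091 clusters of replicate 1, 4665 (91.6%, Wilson 95% interval 90.8 to 92.4%) overlapped a cluster of replicate 2 by at least 1 bp. Of the 4876 clusters of replicate 2, 4613 (94.6%, 93.9 to 95.2%) overlapped one of replicate 1. The lists shared 17.4 Mb, a Jaccard index of covered bases of 0.840. When one list was shifted around each chromosome sequence, overlap averaged 25.8% for replicate 1 and 26.4% for replicate 2, with highest values of 33.2% and 34.4% in 1000 shifts, and the highest Jaccard index was 0.134. The one-sided permutation p was 0.001 for all 3 measures, the smallest that 1000 shifts can give. For the 3927 pairs of clusters that overlapped one to one, the median difference was 59 bp at the start and 55 bp at the end, and both edges lay within 100 bp in 1685 pairs (42.9%). Replicate 2 split 219 clusters of replicate 1 into several, and replicate 1 split 298 clusters of replicate 2. Nothing in the labels says that the replicates came from separate cultures, so the spread between them may be technical.

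Sites that were not shared were mostly narrow and low in score. In replicate 1, 72.4% of the clusters in the lowest scoring 25% of the list were found in replicate 2, against 99.8% in the highest scoring 25%, a difference of 27.3 percentage points (Fisher's exact test, two-sided, p = 3.93e-112). In replicate 2 the shares were 81.05% and 99.5%, a difference of 18.5 percentage points (Fisher's exact test, two-sided, p = 2.24e-65). The 426 unshared clusters of replicate 1 had a median width of 1.73 kb and a median score of 0.52, against 2.67 kb and 1.26 for the shared ones. The 263 unshared clusters of replicate 2 had a median width of 1.71 kb and a median score of 0.42, against 2.72 kb and 1.24. Clusters are not independent replicates, so these p-values describe this pair of lists.

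**Figure D2:**
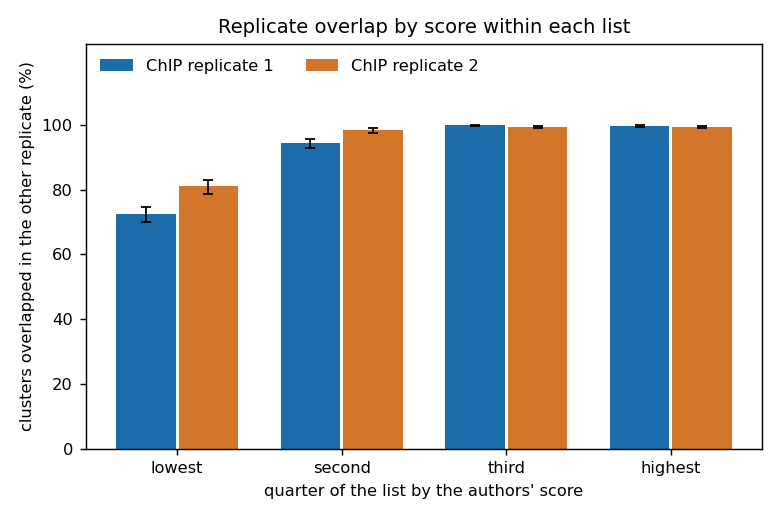
Share of clusters (%) of replicate 1 (blue) and replicate 2 (orange) that overlap a cluster of the other replicate by at least 1 bp, in 4 equal groups of each list ranked by the authors' score. Error bars are Wilson 95% intervals, and the share rises from 72.4% and 81.05% in the lowest group to 99.8% and 99.5% in the highest.

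The combined list held clusters that the replicate lists lacked, most of them narrow and low in score, and lost few. Of its 5309 clusters, 4239 (79.8%, Wilson 95% interval 78.7 to 80.9%) overlapped a cluster in both replicates, 339 one of replicate 1 only and 230 one of replicate 2 only. The remaining 501 (9.44%) overlapped neither, and these were narrow, with a median width of 1.28 kb against 3.11 kb for clusters found in both, and a median score of 0.37 against 1.23. The narrowest cluster was 1001 bp wide in the combined list, against 1301 bp in replicate 1 and 1302 bp in replicate 2. Most of the 501 were thus narrower than any replicate cluster, and for these, added sites cannot be told apart from a lower width limit. The rest were at least as wide as the narrowest replicate cluster, among them one of 2.31 kb. Of these 501, however, 48 (9.58%) scored above the median of the combined list, and 3, all on 2L, reached the scores of the 20 highest sites. These 3 lay from 21429296 to 21431096 and from 21453232 to 21454424, both with a score of 3.51, and from 23008266 to 23010576, with a score of 3.44, and they were named after their values had been seen. In the reverse direction, 5042 of the 5091 clusters of replicate 1 and 4855 of the 4876 clusters of replicate 2 were in the combined list, and 49 and 21 were missing from it. How the combined list was made is not given in the sources used here.

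Nearly all sites lay on the large chromosome arms. The 5 large arms held 4914 clusters in replicate 1 and 4707 in replicate 2, 96.5% of each list. Chromosome 4, the small chromosome, was the most densely marked sequence in each replicate list, with 54.7 clusters per Mb (74 clusters) in replicate 1 and 48.8 (66 clusters) in replicate 2, covering 27.1% and 23.6% of it. Arm 2R followed with 47.3 and 45.7 clusters per Mb, and X with 45.5 and 41.7. Clusters found in both replicates were taken here, and in the windows below, as those of replicate 1 that overlapped one of replicate 2. Among these, however, chromosome 4 held 42.9 per Mb (58 clusters) and 2R 44.5. Chromosome 4 remained the most covered by these, at 24.4%. Arms 3R, 3L and 2L were less densely marked, at 35.5 to 39.6 clusters per Mb in either replicate, and 2L was the lowest of them in both. The sequences of heterochromatin together held 6.90 and 6.68 clusters per Mb, and U held 3.88 and 4.08. Repeated sequence limits how well reads can be placed there, and the treatment of such reads is not given in the sources used here. These differences between arms other than X were not tested.

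**Figure D3:**
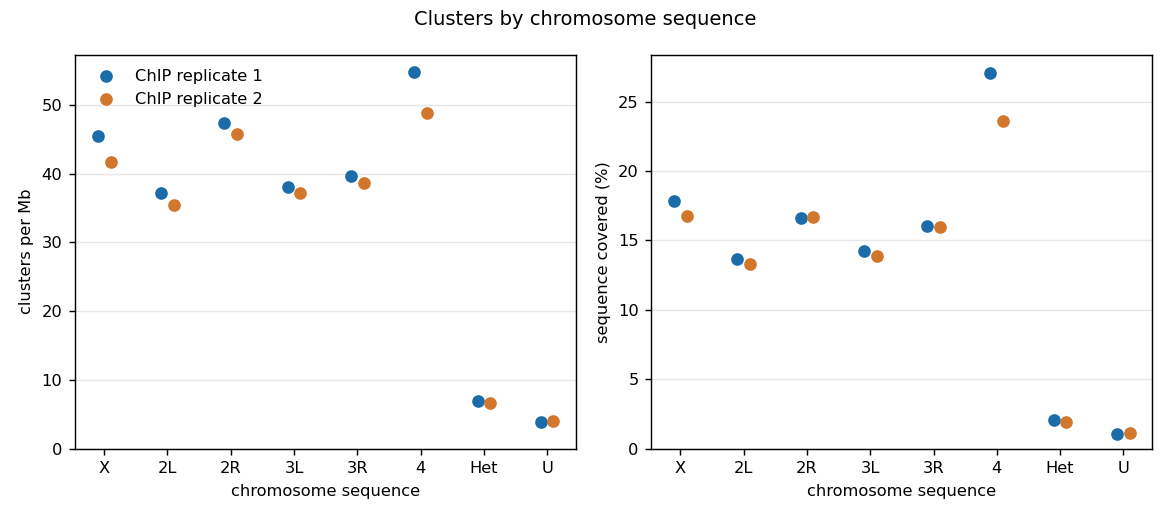
Clusters per Mb (left) and percent of sequence covered by clusters (right) by chromosome sequence, with replicate 1 in blue and replicate 2 in orange. Het stands for the heterochromatin sequences together. Chromosome 4 is highest in both replicates, with 27.1% and 23.6% covered, and Het and U are lowest of the sequences shown. The sequence Uextra, which held no cluster in any list, is not shown.

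The labels call the cells male, which raises the question of how the X compares with the autosomes. Clusters found in both replicates numbered 40.2 ± 11.9 per 1 Mb window on X (SD, 22 windows) and 37.8 ± 11.7 on the large autosome arms (SD, 95 windows), a ratio of 1.07 that did not pass the test (two-sided permutation of windows, p = 0.382). They covered 16.9 ± 5.08% of X windows and 14.7 ± 5.43% of autosome windows, a ratio of 1.15 that did not pass either (permutation p = 0.0821). With each list alone the ratio of covered sequence was 1.19 in replicate 1 (permutation p = 0.0275), 1.13 in replicate 2 (permutation p = 0.127) and 1.23 in the combined list (permutation p = 0.00644). The ratio of clusters per window was 1.14 in replicate 1 (permutation p = 0.0596), 1.08 in replicate 2 (permutation p = 0.301) and 1.15 in the combined list (permutation p = 0.0389). X was higher in all 8 of these comparisons, and none passed Benjamini-Hochberg adjustment over the 8, the lowest adjusted p being 0.0515. The lists share most of their clusters, and both measures use the same clusters, so the 8 comparisons are not independent of each other. Windows are not independent replicates, and the permutation of windows was chosen after the densities had been seen.

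Density also varied along the arms. Among full 1 Mb windows, clusters found in both replicates were fewest on 2L from 14 to 15 Mb and on 3L from 23 to 24 Mb, with 9 each, and then on 2L from 17 to 18 Mb, with 15. They were most numerous on 2R from 3 to 4 Mb, with 63, on 2R from 5 to 6 Mb, with 60, and on 3R from 20 to 21 Mb, with 59. The richest X windows, from 6 to 7 Mb and from 15 to 16 Mb, held 58 each, and the poorest, from 14 to 15 Mb, held 18. These windows were picked for their counts and were not tested.

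**Figure D4:**
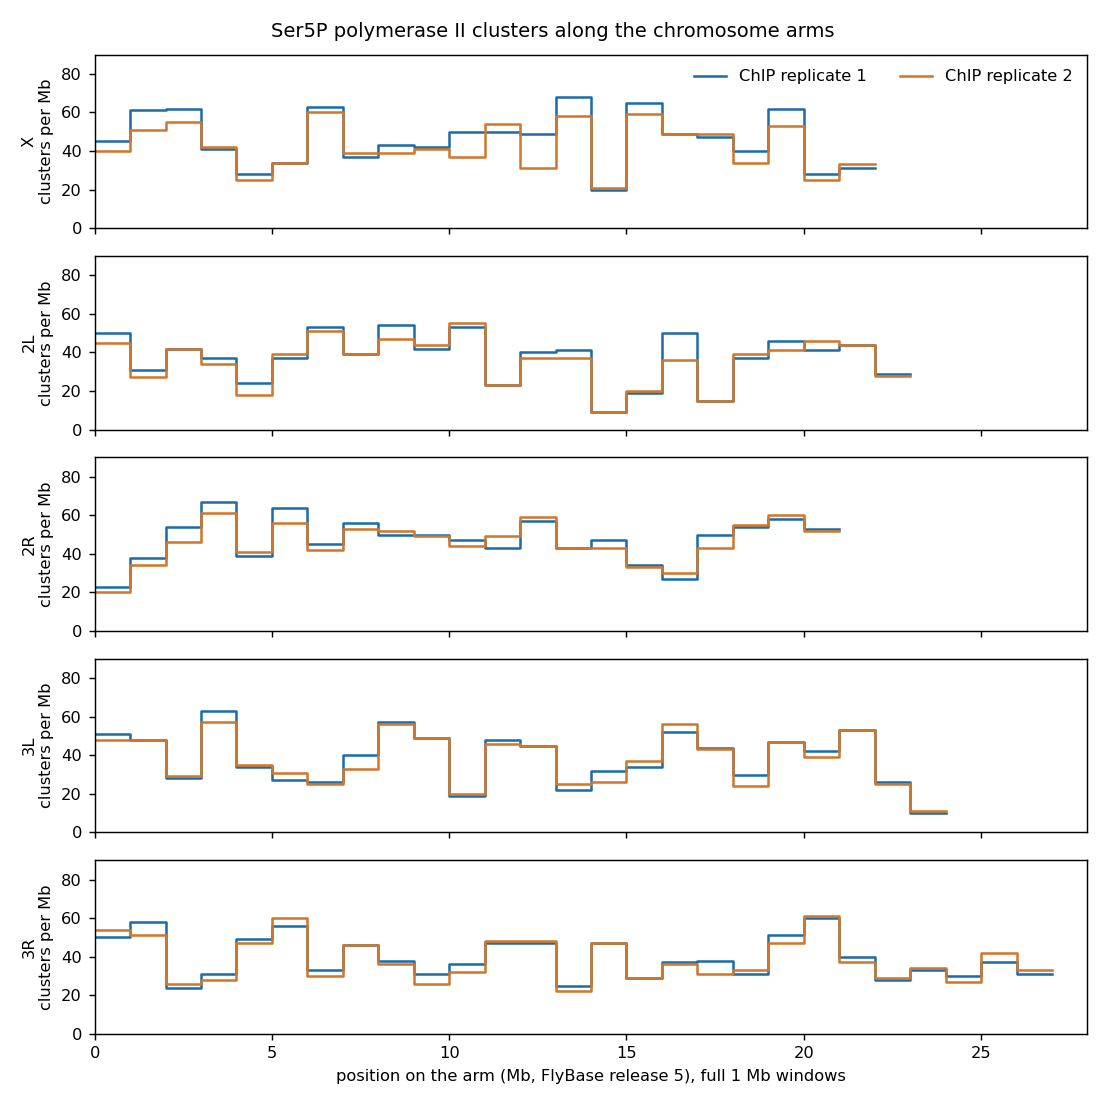
Clusters per 1 Mb window along X, 2L, 2R, 3L and 3R, with position in Mb on FlyBase release 5 on the horizontal axis, replicate 1 in blue and replicate 2 in orange. The replicates rise and fall together along each arm, with low points on 2L from 14 to 15 Mb and on 3L from 23 to 24 Mb.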

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

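All tests in this part were chosen after the results had been seen. The combined list marked 18 regions as depleted, and the comparisons above did not use these regions. They were between 1.46 and 1.88 kb wide, 7 lay on 2R, 7 on 3L, 2 on 3R, 1 on 2L and 1 on X, and their scores ran from -0.116 to -0.000168. Of these 18 regions, 14 (77.8%) overlapped an enriched cluster of at least 1 replicate, 6 one of replicate 1 and 10 one of replicate 2, 2 of them one of both. After circular shifts, 4.03 of the 18 did so on average and 12 at most (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). This argues against lower signal than input in both replicates as the account of the whole set, since 14 regions were called enriched in a replicate. A candidate explanation, which the lowest score of -0.116 leaves open, is that the regions were picked out as different by some other measure and that the mark follows the sign of a score near 0. The caller and its criteria are not given in the sources used here, and no biological explanation was tested.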

How the results depend on the processing

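Of 59 alternative values for 13 results, 44 kept their direction and side of the threshold, moved by less than the spread or, for numbers of clusters, stayed within 1.5 times the original, 5 moved past the threshold, 10 moved by more than these limits, and none reversed or fell below the threshold. Taking only the upper 50% of each list by score left 2545, 2438 and 2654 clusters in replicate 1, replicate 2 and the combined list by construction, raised the mean of the median widths from 2.57 to 3.42 kb, lowered the covered sequence from 19.1 to 12.4 Mb and raised the share of combined clusters found in both replicates from 79.8 to 82.7%. Merging clusters within 1 kb gave 4221, 4146 and 4341 clusters, a median width of 2.84 kb, 19.4 Mb and 84.1%, and the large arms alone gave 4914, 4707 and 5086 clusters and 18.4 Mb. Replicate overlap stayed beyond all shifts under every rule run, and was lowest, at 83.1% for replicate 1 and 86.8% for replicate 2, with reciprocal overlap of at least 50%. The ratio of X to autosomes was the only result whose call changed. For clusters per Mb it was 1.07, and passed the threshold, unadjusted, with the combined list (1.15, permutation p = 0.0389) but not with the upper 50% of each list (1.17, permutation p = 0.0577) or merged clusters (1.02, permutation p = 0.767). For covered sequence it was 1.15 and passed the threshold, unadjusted, with the upper 50% of each list (1.29, permutation p = 0.00971), merged clusters (1.18, permutation p = 0.0436), the combined list (1.23, permutation p = 0.00644) and without replicate 2 (permutation p = 0.0275). Leaving out each replicate gave ratios of 1.13 to 1.19 for covered sequence and 1.08 to 1.14 for clusters. With windows of 2 Mb, chosen after seeing the data, the ratios were 1.06 (permutation p = 0.433) and 1.15 (permutation p = 0.0912), and without the 2 poorest windows, also chosen then, 1.05 (permutation p = 0.493) and 1.13 (permutation p = 0.111). Except where construction sets the value, the cause was not tested. The 500 bp minimum removed nothing, as the narrowest cluster was 1001 bp wide. Its values are counted among the 44 but say nothing about stability. Densities per annotated gene and all alternatives on start sites, gene bodies, gene lists and motifs were not run, for want of an annotation of release 5. No paired analysis was possible because only the ChIP libraries have cluster lists and no library enters a model. The unknown depth limits any comparison of cluster numbers or widths between the replicates.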

Other observations

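The spans and runs in this part, and all tests in it, were chosen after the data had been seen. Long stretches of the arms carried no cluster in any of the 3 lists. There were 35 such spans of at least 200 kb, 9.15 Mb in all, with 10 on 2L, 10 on 3R, 7 on 3L, 5 on X and 3 on 2R. The longest ran over 368.7 kb of 2L from 15772129 to 16140853, followed by 368.4 kb of X from 20529635 to 20898061 and 362.4 kb of 2L from 4465857 to 4828285. On 3R a span of 327.7 kb ran from 12479097 to 12806783. How much of these spans is repeated sequence, where reads are hard to place, was not examined.

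A run of evenly spaced clusters lay on 2L near one of the highest scoring sites. Replicate 1 had 4 clusters from 21463344 to 21480477 whose spacing was 5041 to 5045 bp, and replicate 2 had 4 from 21463340 to 21480668 at 5041 to 5047 bp. The combined list had 6 from 21453232 to 21480668 at 5040 to 5058 bp. No other run of at least 4 clusters with spacing equal within 1% was found in any list. With the gaps between clusters shuffled 100 times, a list held 0.21, 0.17 and 0.14 runs within 1% on average and at most 1. Runs as long and as even as those seen were rarer, in 1 of 1000 shuffles for replicate 1 and in 0 of 1000 for replicate 2 and for the combined list, with the evenness set from the runs themselves. The length of 6 in the combined list rests on 2 clusters that overlap no cluster of either replicate, from 21453232 to 21454424 and from 21458278 to 21460484. These belong to 6 combined-list clusters found in neither replicate that lay at this locus, between 21419966 and 21495546, with scores from 2.96 to 3.51, and 2 of the 3 that reached the scores of the 20 highest sites were among them. Whether the recurrence at the same place in both replicates exceeds their general overlap was not tested. Whether the run lies in repeated sequence, which limits how well reads can be placed, was not examined. The clusters of the run therefore need not be separate sites of the polymerase.

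Few X clusters had low scores. Clusters of a list are not independent replicates, so Fisher's exact tests and odds ratio intervals here and in the next paragraph describe these lists. Of 1020 X clusters of replicate 1, 27 (2.65%) were in the lowest 10% of the list's scores, against 467 of 3894 autosome clusters (12.0%; Fisher's exact test, two-sided, p = 3.07e-23). The shares were 2.89% and 12.0% in replicate 2 (Fisher's exact test, p = 2.51e-20) and 2.26% and 12.1% in the combined list (Fisher's exact test, p = 2.73e-27). A constant added to the X scores of the listed clusters would raise the 5th percentile and the median alike. Instead the 5th percentile was raised more, by 0.097 in replicate 1 (bootstrap 95% interval 0.0123 to 0.188) and 0.146 in the combined list (0.0343 to 0.256), which argues against such a constant there. In replicate 2 the difference was 0.0761 (-0.00807 to 0.164), which spans 0, so such a constant cannot be told apart from a change at the low end. A constant present before calling could also let weaker X regions into the list, so the comparison cannot exclude that. A candidate explanation is that fewer reads stand behind each score on X, so that a low ratio does not reach the caller's threshold; tied scores, which few reads would give, were more common on X in each list, with odds ratios of 1.61, 1.77 and, in the combined list, 1.42 (Fisher's exact test, p = 0.0445). All cells are male, so no biological explanation was tested.

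X clusters of replicate 1 were missing from replicate 2 more often than autosome clusters, 130 of 1020 (12.7%) against 262 of 3894 (6.73%; Fisher's exact test, two-sided, p = 2.42e-09), a ratio of 1.89 (bootstrap 95% interval over 1 Mb windows 1.34 to 2.62). In the reverse direction the shares were 5.13% and 5.17% (Fisher's exact test, p = 1), but within 10 equal score groups X clusters were missing more often in both directions, with odds ratios of 4.32 for replicate 1 (95% interval 3.24 to 5.78) and 2.08 for replicate 2 (1.42 to 3.04). Few X clusters were low in score, with 2.65% of those of replicate 1 in the lowest 10% of its scores, against 12.0% of autosome clusters. Neither these shares nor the score groups can exclude marginal calls on X. A score may not measure distance from the caller's threshold alike on X and autosomes. The window from 12 to 13 Mb, where 22 of 49 clusters were missing, does not account for the whole difference. Without it the odds ratio was 1.73 (Fisher's exact test, p = 9.79e-06). X was over-represented among the missing clusters of replicate 1 against those of replicate 2 (odds ratio 2.02, Fisher's exact test, p = 0.000266), which rests on the same counts. It cannot exclude a greater number of calls everywhere in replicate 1. If fewer reads stand behind X scores, such calls need not split missing clusters alike. A difference between the libraries or their inputs in depth or in reads on X, or in X copy number between cultures, stays open and was not tested.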
